A study of Gallus gallus with 16 samples.

How the data were processed

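Bulk RNA sequencing was carried out on chick (Gallus gallus) vagal neural crest at Hamburger and Hamilton stage 18, per the labels. Neural crest is an embryonic cell population that leaves the dorsal neural tube, and its vagal part contributes, among others, to the enteric nervous system and the heart. Embryos had been electroporated with a plasmid for Cas9 and the fluorescent protein Citrine together with U6 plasmids for guide RNAs, and Citrine-positive cells had been sorted. Per the labels' protocols, vagal regions were dissociated and sorted, while the extraction text speaks of dorsal neural tubes cut along the midline. Libraries were made with the SMART-Seq v4 low-input kit and Nextera XT from RNA with an integrity number above 6 and sequenced as paired reads of 40 bp on a NextSeq500.

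The 16 libraries fell into 6 groups by their titles. The control carried Cas9 without a guide plasmid (2 libraries). The sox3 group had 2 guide plasmids (2 libraries), the msx1 group 1 (3 libraries), the sox10 group 2 (3 libraries), the tfap2b group 2 (3 libraries) and the double sox10 and tfap2b group 3 (3 libraries). The double group carried both tfap2b guides and 1 of the 2 sox10 guides. No label says that the libraries of a group came from separate embryos or days, so p-values measure only the spread between these samples, which may be technical.

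The deposited table held whole-number read counts per gene for each library, not normalized, with gene spans, exon positions and exonic length. Per the submitters' processing notes, STAR 2.4.2a, Subread 1.4.5 with featureCounts, and DESeq2 were used on the galGal5 assembly. Whether the counting used strand is not given in the sources used here, so overlapping genes are marked as uncertain. Total counts ranged from 5721022 to 24929531 per library. The table listed 24881 features, of which 7091 had no count in any library. The 37 mitochondrial features were at 0 counts in every library.

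All features carried gene IDs without symbols. The reference table used here (GRCg7b) matched 0 of the IDs, and the files do not pair them with names. The check of the 4 targeted genes, the tests of 21 gene lists (neural crest, neuronal, glial, mesenchymal, blood and other cell types, and stress pathways) and the part of the rule for named genes that needs a symbol were therefore not run. In their place, 12 groups of genes were formed by location and structure, chosen after the table was seen. These were macrochromosomes (1 to 5), intermediate chromosomes (6 to 10), microchromosomes (11 to 33), Z, W, unplaced, 5 equal bins of exonic length and single-exon genes. Coordinates are those of the deposited table.

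Differential expression was computed from the deposited counts with the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3). All 16 libraries entered 1 fit with group as the sole factor, TMM scaling, the default expression filter (14081 genes kept) and robust estimation. Genes with a Benjamini-Hochberg adjusted p under 0.05 in this test are called changed, and every adjusted p for a gene comes from it. The comparisons were 5 groups against the control, the double group against each single group, and the non-additivity contrast (double minus sox10 minus tfap2b plus control, log2 scale), 8 in all. Standard errors are the log2 fold change divided by the square root of the F statistic. The common biological coefficient of variation was 0.478 with 10 residual degrees of freedom. The fit, the threshold, its alternatives and the rule for named genes were fixed before the data were examined.

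The rule took, per comparison and direction, genes past the threshold with a mean of at least 5 CPM (counts per library scaled to the TMM library size) in 1 of the groups and no overlap between libraries, ranked by fold change. Without symbols, at most 2 per direction and comparison are printed, and the same rule was used for the other comparisons. For the non-additivity contrast, however, the condition of no overlap between libraries was not applied. The genes of a region on chromosome 14 were singled out after their values were seen, and their levels per library are CPM of the library total, without TMM. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with its 95% exact binomial interval. Intervals and floors cover counting error only. Gene groups were tested with camera (preset correlation 0.01, adjusted over the 12 groups) and again with an estimated correlation.

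The fit was tested on simulated counts with 200 changed genes. For sox10 against the control (13538 genes in the fit) it recovered 6% of 2-fold, 38% of 4-fold and 68% of 8-fold changes. For sox3 against the control (13529 genes) these shares were 2%, 36% and 64%. Each simulated gene had the same spread in all groups, unlike the replicates in the data. With only 200 changed genes, the adjusted threshold was also stricter than in the real sox10 comparison, where 6538 genes passed. The shares therefore do not give the sensitivity of that comparison. Overlaps between comparisons that share the control were set beside 30 simulated draws of unchanged groups. Genes detected per library were counted after thinning each library to 5721022 counts.

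Replicate pairs were compared before averaging. All 14 differed beyond sampling noise (chi-square per degree of freedom 7.42 to 119), so none was taken as 1 library sequenced again. This does not show that the libraries came from separate samples, since repeat libraries of 1 pool would also differ by more than counting noise. Each library was counted as a replicate, and the close pairs were also summed as an alternative. Replicates 1 and 2 of the control, sox3 and msx1 groups were closer to each other (scaled median absolute deviation of log2 ratios 0.212 to 0.263) than the other 11 pairs (0.336 to 0.844), while counting alone would give 0.0653 to 0.0972.

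Alternatives fixed in advance were RLE size factors, no filter, DESeq2 1.42.0, limma-voom with quality weights, fitting the compared groups alone, a replicate block and leaving out each library. Further alternatives chosen after seeing the data removed trends with length and chromosome class, in a first form that also shifted whole libraries and in a second that recentred them, left out Z and W genes, thinned the counts, summed the close pairs, took the sox3 or msx1 group as the reference, or gave each group of a pair its own control library. The recentred form was chosen after the result of the first form was seen.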

Results

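The data were read counts per gene in 16 libraries of sorted chick neural crest cells in which SOX3, MSX1, SOX10 or TFAP2B, all transcription factors, or SOX10 and TFAP2B together, had been targeted with CRISPR/Cas9. Control embryos received Cas9 without guides. The comparisons ask which transcripts differ after targeting each of these putative core factors. Total counts were 19355001 and 22142722 in the control, 6049569 and 14947150 in the sox3 group, and 5721022 to 24929531 in the msx1 group. They were 9112556 to 10263454 in the sox10 group, 11151747 to 16951686 in the tfap2b group and 10950236 to 16510003 in the double group. The targeted genes themselves were not analysed here, since the gene IDs are not paired with names.

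Libraries of the control, sox3 and msx1 groups lay at one end of the first principal component (45.1% of variance, scores -120 to -81.4). Those of the sox10, tfap2b and double groups lay at the other (34.6 to 132). At an equal depth of 5721022 counts, 14470 and 14528 genes had a count in the 2 control libraries, 14538 ± 94.8 (n = 2) in the sox3 group and 14803 ± 172 (n = 3) in the msx1 group. The sox10 group had 12690 ± 132, the tfap2b group 13566 ± 314 and the double group 13467 ± 296 (SD, n = 3 each). The 100 most abundant genes took 12.3% ± 0.468 of counts in the control (SD, n = 2) and 19.5% ± 0.387 in the sox10 group (SD, n = 3).

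**Figure D1:**
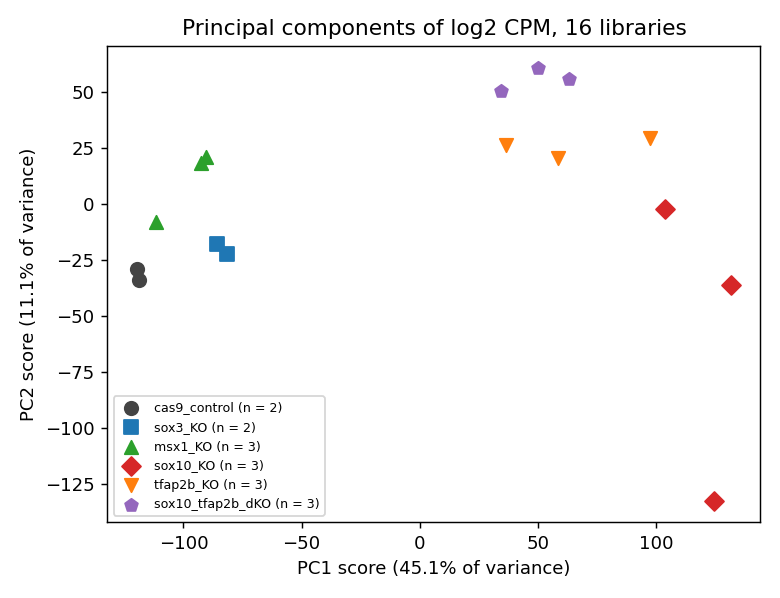
Each point is 1 library, placed by its scores on the first principal component (x axis, 45.1% of variance) and the second (y axis, 11.1%) of log2 CPM; colour and shape give the group. The control, sox3 and msx1 libraries have negative scores on the first component and the other 9 libraries positive ones.

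In the sox3 group, 81 genes were higher and 10 lower than in the control, of 14081 tested. ENSGALG00000016498 (galGal5 chromosome 3, 104544323 to 104575302, 14 exons) rose from 0.0460 ± 0.0650 CPM in the control to 60.6 ± 4.39 CPM (SD, n = 2 each). With 2 control counts, the ratio was 1478 (95% interval 409 to 12218). ENSGALG00000029375 (chromosome 8, 28469647 to 28479499, 4 exons) had 0 control counts and 12.6 ± 1.99 CPM (SD, n = 2) in the sox3 group, at least 209-fold higher. These rises were not particular to the sox3 group, since the sox10 group held 32.8 and 11.2 CPM of the 2 genes on average. Means in the msx1, tfap2b and double groups were 0.553 to 4.08 CPM for the first and 0.380 to 3.58 CPM for the second. ENSGALG00000006130 (chromosome 20, 9900969 to 9911514, 5 exons) fell from 30.9 ± 4.13 to 3.17 ± 0.565 CPM (SD, n = 2 each; log2 fold change -3.29, SE 0.55). ENSGALG00000010461 (chromosome 6, 34199151 to 34316515, 18 exons) fell from 211 ± 9.23 to 52.5 ± 3.36 CPM (SD, n = 2 each; log2 fold change -2.01, SE 0.44). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p of these genes was 0.00363, 0.0359, 0.0104 and 0.0480.

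Of the 91 genes changed in the sox3 group, 46 of the higher and 6 of the lower lay on macrochromosomes, and 18 and 3 on microchromosomes. No group of genes by location or length passed camera there (689 Z genes had the smallest adjusted p, 0.0745; 0.684 with an estimated correlation). The number and the balance of directions varied with the fit: 2152 genes were higher and 2113 lower when the sox3 and control libraries were fitted alone, and 1785 higher and 2424 lower by limma-voom with quality weights. With the close pairs of libraries summed, which leaves 1 sample per group, 1 gene passed. Without sox3 replicate 1 or 2 it was 20 or 21, and without control replicate 1 or 2 it was 7 or 5. ENSGALG00000016498 lost its call without either control library (adjusted p 0.0961 and 0.165), and the other 3 named genes lost theirs without any 1 of the 4 libraries (adjusted p of the 4 genes over all alternatives 2.00e-11 to 1). ENSGALG00000010461 lost its call in 9 of 15 alternatives, among them RLE size factors (0.0508) and the replicate block (0.0729), and was at 37.5 to 74.3 CPM on average in all 5 targeted groups.

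In the msx1 group, 151 genes were higher and 248 lower than in the control. ENSGALG00000035557 (chromosome 12, 6139852 to 6142332, 4 exons) fell from 38.9 ± 5.90 CPM (SD, n = 2) to 0.512 ± 0.255 CPM (SD, n = 3; log2 fold change -6.27, SE 1.11). ENSGALG00000027501 (chromosome 10, 19886093 to 20028017, 21 exons, overlapping another gene and therefore uncertain) fell from 23.9 ± 1.10 to 1.95 ± 0.932 CPM (SD, n = 2 and 3). ENSGALG00000032349 (chromosome 11, 11674123 to 11703375, 12 exons) rose from 0.108 ± 0.0430 to 31.4 ± 26.0 CPM (SD, n = 2 and 3; log2 fold change 8.10, SE 1.75). ENSGALG00000002549 (chromosome 8, 3620501 to 3624059, 5 exons) had 0 control counts and 5.03 ± 4.39 CPM (SD, n = 3), at least 76.2-fold higher. Both genes that fell were low in every targeted group, at group means of 0.0863 to 3.80 CPM for the first and 0.173 to 2.46 CPM for the second. Both that rose were also above the control on average in every other targeted group. Group means there were 3.06 to 33.7 CPM for ENSGALG00000032349 and 3.57 to 11.1 CPM for ENSGALG00000002549. The adjusted p of the 4 genes was 0.00617, 0.0414, 0.0193 and 0.0253 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

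Among the 4402 genes with at least 50 CPM in the control, 30 were higher and 186 lower in the msx1 group. Among the 2183 genes under 1 CPM in the control, 18 were higher and 0 lower. The 23 W-linked genes tested had a median log2 fold change of 0.98 (camera adjusted p = 0.0324, and adjusted p = 0.924 with an estimated correlation), with 0 of them past the threshold singly. Counts on W genes were 842 and 843 CPM in msx1 replicates 1 and 2, 229 CPM in replicate 3, and 364 and 382 CPM in the control. By DESeq2, 532 genes were higher and 521 lower, while lower genes remained in excess with the msx1 and control libraries alone (1089 higher, 1178 lower), by limma-voom (2193 and 3199), with RLE size factors (159 and 221) and without a filter (129 and 235). The number of changed genes was 2267 with the msx1 and control libraries alone, 126 without msx1 replicate 1, 165 without replicate 2, and 42 or 63 without control replicate 1 or 2. Each of the 4 named genes lost its call without control replicate 1 or 2 (adjusted p 0.0505 to 0.324), and all but ENSGALG00000035557 also without msx1 replicate 1 or 2 (0.0530 to 0.198). ENSGALG00000027501 also lost its call without msx1 replicate 3 (0.0672) and with the replicate block (0.0882; adjusted p of the 4 genes over all alternatives 3.44e-10 to 1).

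**Figure D2:**
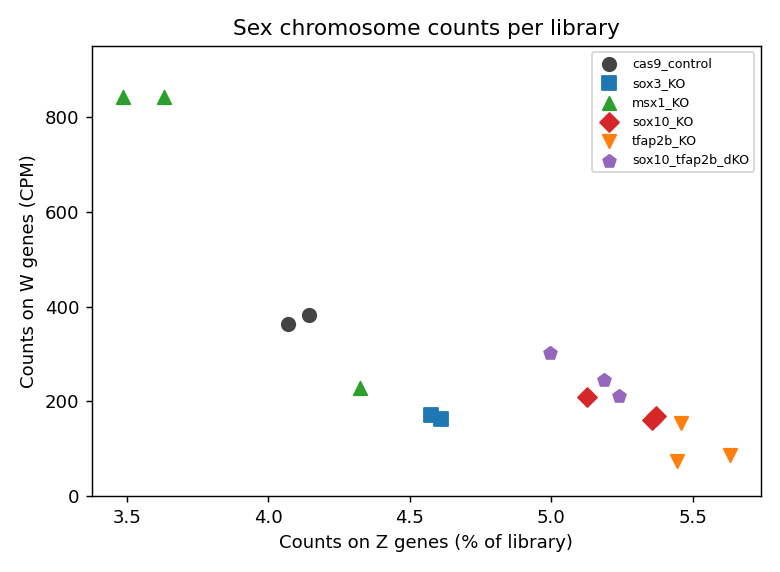
Each point is 1 library, placed by the share of its counts on Z genes (x axis, percent) and its counts on W genes (y axis, CPM); colour and shape give the group. The msx1 libraries of replicates 1 and 2 lie at 842 and 843 CPM on W, above the other 14 libraries (74.1 to 382 CPM).

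**Figure D3:**
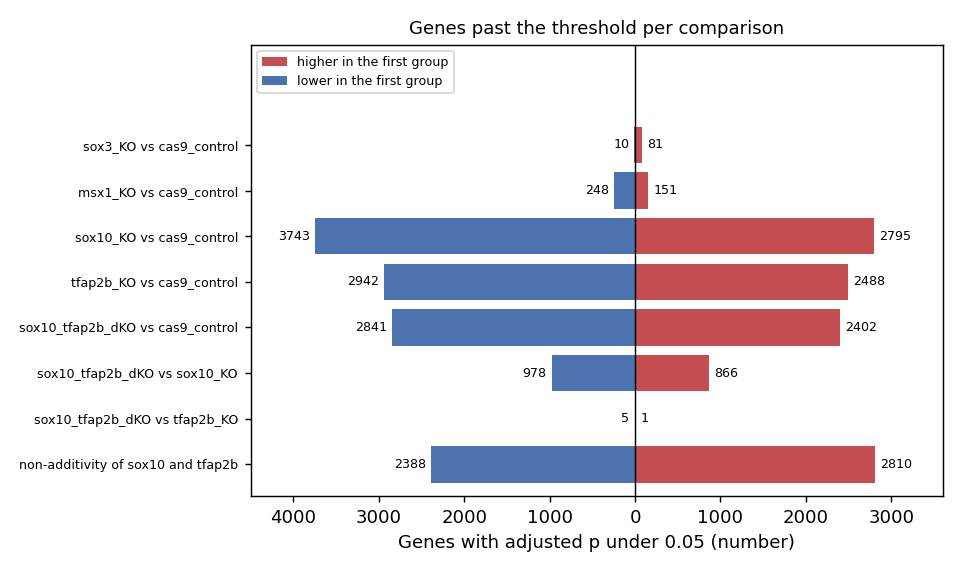
Bars give the number of genes past the threshold in each comparison (x axis, genes), to the right for genes higher in the first group named and to the left for genes lower; for non-additivity, the direction is that of the contrast. Changed genes number 91 and 399 in the sox3 and msx1 groups and 6538, 5430 and 5243 in the sox10, tfap2b and double groups.

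In the sox10 group, 2795 genes were higher and 3743 lower than in the control, 46.4% of those tested. ENSGALG00000026671 (chromosome 9, 15899244 to 15900485, 3 exons) had 29.5 ± 2.48 CPM in the control (SD, n = 2) and 0 counts in all 3 sox10 libraries, at least 229-fold lower. ENSGALG00000044235 (chromosome 4, 33261652 to 33262873, 2 exons, overlapping another gene and therefore uncertain) had 37.1 ± 2.82 CPM in the control (SD, n = 2) and 0 counts in the sox10 group, at least 291-fold lower. The largest rises were of ENSGALG00000017347 (chromosome 1, 194562710 to 194576539, 6 exons, overlapping another gene and uncertain) and ENSGALG00000031597 (chromosome 14, 12160597 to 12161521, 3 exons). The first had 0.304 ± 0.170 CPM in the control (SD, n = 2) and 3499 ± 1015 in the sox10 group (SD, n = 3), and the second 0.369 ± 0.194 and 3206 ± 1153. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 1.50e-05 and 0.000545 for the genes that fell, and 0.00728 and 0.0108 for those that rose.

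ENSGALG00000044235 was also below the control in every other targeted group, at group means of 0.514 to 4.33 CPM. ENSGALG00000026671 was low in the tfap2b and double groups (0.841 and 1.03 CPM on average). In the sox3 and msx1 groups it was at 18.9 and 21.9 CPM on average. Both genes that fell kept their call in 18 of 18 alternatives. Both that rose lost it without control replicate 1 or 2 (adjusted p 0.0666 to 0.0931) and with the sox3 group as the reference, in which they were also abundant (adjusted p 0.766 and 0.846; over all alternatives of these genes 7.36e-14 to 0.846). ENSGALG00000031597 lies in a region of chromosome 14 (12156905 to 12164434) with 3 tested genes, and this region held 8102 to 14178 CPM in the sox10 libraries and 8510 and 13475 CPM in the sox3 libraries. It held 2089 to 4592 CPM in the tfap2b libraries, 45.8 to 2938 CPM in the double libraries, 6.99 to 712 CPM in the msx1 libraries and 1.76 and 2.30 CPM in the control libraries. Levels of the region went with those of the chromosome 1 gene, which was at 2025 to 3531 CPM in the sox10 group and at 0.207 and 0.497 CPM in the control. None of the 4 genes passed the threshold in the sox3 group (adjusted p 0.166 to 0.219), at log2 fold changes of 12.13 to 12.63 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 2 against 2).

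**Figure D4:**
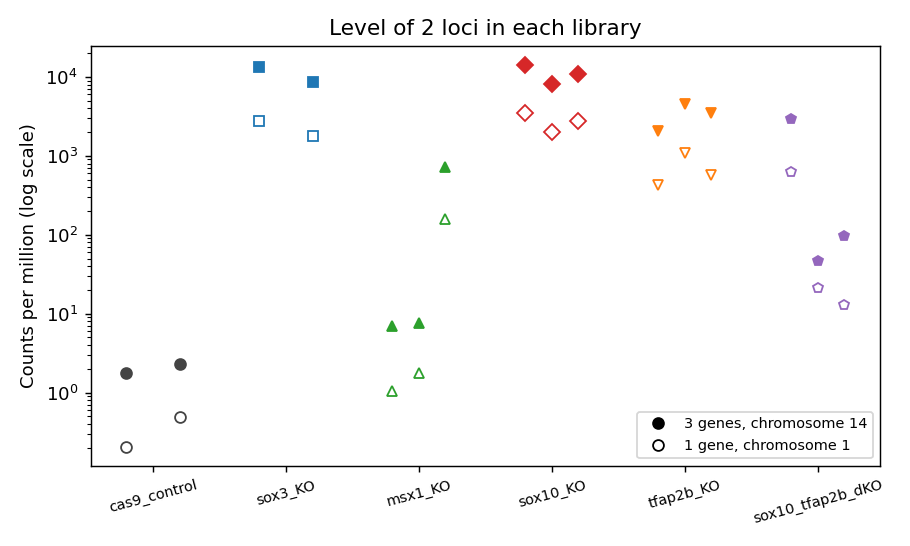
Each filled symbol is the summed level of the 3 genes on chromosome 14 (12156905 to 12164434), and each open symbol that of ENSGALG00000017347 on chromosome 1, in 1 library (y axis, CPM on a log scale; x axis, group). The control libraries are at 1.76 and 2.30 CPM for the chromosome 14 region, and the sox10 libraries at 8102 to 14178 CPM.

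Changes in the sox10 group reached abundant genes: of the 4402 with at least 50 CPM in the control, 1433 were higher and 1571 lower. Genes on microchromosomes had a median log2 fold change of -0.64, against -0.07 on macrochromosomes, with 811 of 4776 higher and 1581 lower (camera adjusted p = 0.111, and 0.320 with an estimated correlation). The 2815 genes with over 3339 bp of exons had a median of -0.67, with 292 higher and 974 lower (camera adjusted p = 0.00397, and adjusted p = 0.261 with an estimated correlation). The 2819 genes with at most 1096 bp had a median of 0.36 and a mean of -0.12, with 679 higher and 515 lower (camera adjusted p = 0.0362 for the upward direction, and adjusted p = 0.320 with an estimated correlation). The number of changed genes was 3608 with the close pairs of libraries summed and 4175 with the sox10 and control libraries alone. More genes were lower than higher with RLE size factors as well (2981 higher, 3528 lower), while with trends of length and chromosome class removed and libraries not recentred, which shifts whole libraries, 4155 were higher and 2244 lower.

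In the tfap2b group, 2488 genes were higher and 2942 lower than in the control. ENSGALG00000000371 (chromosome 27, 2399395 to 2423289, 13 exons) had 20.4 ± 6.73 CPM in the control (SD, n = 2) and 0 counts in the tfap2b libraries, at least 259-fold lower. ENSGALG00000027330 (chromosome 13, 13093269 to 13097891, 2 exons) had 13.0 ± 0.550 CPM in the control (SD, n = 2) and 0 counts in the tfap2b libraries, at least 162-fold lower. ENSGALG00000043234 (chromosome 14, 12163617 to 12164434, 3 exons) rose from 0.685 ± 0.123 to 1827 ± 783 CPM (SD, n = 2 and 3) and ENSGALG00000017347 from 0.304 ± 0.170 to 804 ± 475 CPM (SD, n = 2 and 3). Adjusted p was 5.90e-05, 0.000258, 0.0165 and 0.0159 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Both genes that fell were also below the control in every other targeted group. Group means there were 0 to 9.48 CPM for the first and 0.0428 to 3.37 CPM for the second. The genes that fell kept their call in 18 of 18 alternatives, while those that rose lost it without control replicate 1 or 2 (adjusted p 0.113 to 0.122) or against the msx1 group (0.0968 and 0.104), and lay below the sox3 group (log2 fold change -1.22 and -1.33; adjusted p of the 4 genes over all alternatives 4.58e-12 to 0.671).

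Microchromosome genes had a median log2 fold change of -0.56 in the tfap2b group (686 higher, 1371 lower; camera adjusted p = 0.0101, and adjusted p = 0.131 with an estimated correlation). Genes with over 3339 bp of exons had a median of -0.63 (235 higher, 881 lower; camera adjusted p = 0.000187, and adjusted p = 0.106 with an estimated correlation). Z-linked genes had a median of 0.29, with 163 of 689 higher and 85 lower (camera adjusted p = 0.0101, and adjusted p = 0.234 with an estimated correlation). W-linked genes had a median of -1.91 (camera adjusted p = 0.0349, and adjusted p = 0.421 with an estimated correlation), with W counts of 154, 87.3 and 74.1 CPM in the 3 libraries. The number of changed genes was 3527 or 3420 without control replicate 1 or 2 and 2506 with the close pairs summed. With trends of length and chromosome class removed and libraries not recentred, 3355 genes were higher and 1963 lower.

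In the double group, 2402 genes were higher and 2841 lower than in the control. ENSGALG00000033974 (chromosome 1, 10650557 to 10710329, 18 exons) had 48.8 ± 0.209 CPM in the control (SD, n = 2) and 0 counts in the double libraries, at least 622-fold lower. ENSGALG00000019018 (chromosome 22, 2263412 to 2265233, 2 exons) had 10.5 ± 1.48 CPM in the control (SD, n = 2) and 0 counts, at least 132-fold lower. ENSGALG00000002549, also higher in the msx1 group, had 9.90 ± 7.17 CPM (SD, n = 3) against 0 control counts, at least 142-fold higher. Its means in every other targeted group were 3.57 to 11.1 CPM. ENSGALG00000031430 (chromosome 8, 5128027 to 5133557, 10 exons) had 10.9 ± 10.4 CPM (SD, n = 3) against 0 control counts, at least 151-fold higher. Adjusted p was 0.000114, 0.00286, 0.00159 and 0.0138 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Both genes that fell were also below the control in every other targeted group. Group means there were 0.229 to 10.1 CPM for the first and 0 to 1.30 CPM for the second. The genes that fell kept their call in 18 of 18 alternatives; ENSGALG00000002549 lost it with the sox3 or msx1 group as the reference (adjusted p 0.398 and 0.507), and ENSGALG00000031430 without control replicate 1 or 2 (0.0887 and 0.0950) or against the msx1 group (0.407; over all alternatives of these genes 3.04e-13 to 0.507).

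Microchromosome genes had a median log2 fold change of -0.47 in the double group (649 higher, 1263 lower; camera adjusted p = 0.0336, and adjusted p = 0.128 with an estimated correlation). That call was lost without double replicate 2 (adjusted p = 0.0601) or control replicate 1 (0.0687), with a range over alternatives of 0.0197 to 0.128. Genes with over 3339 bp of exons had a median of -0.48 (273 higher, 800 lower; camera adjusted p = 0.00599, and adjusted p = 0.128 with an estimated correlation). The number of changed genes was 3214 or 3048 without control replicate 1 or 2, 2007 with the close pairs summed and 8504 by limma-voom with quality weights. With trends of length and chromosome class removed and libraries not recentred, 3319 genes were higher and 2077 lower. With genes at 0 counts in a group placed at their bound, the microchromosome medians were -0.64, -0.56 and -0.47 in the sox10, tfap2b and double groups.

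**Figure D5:**
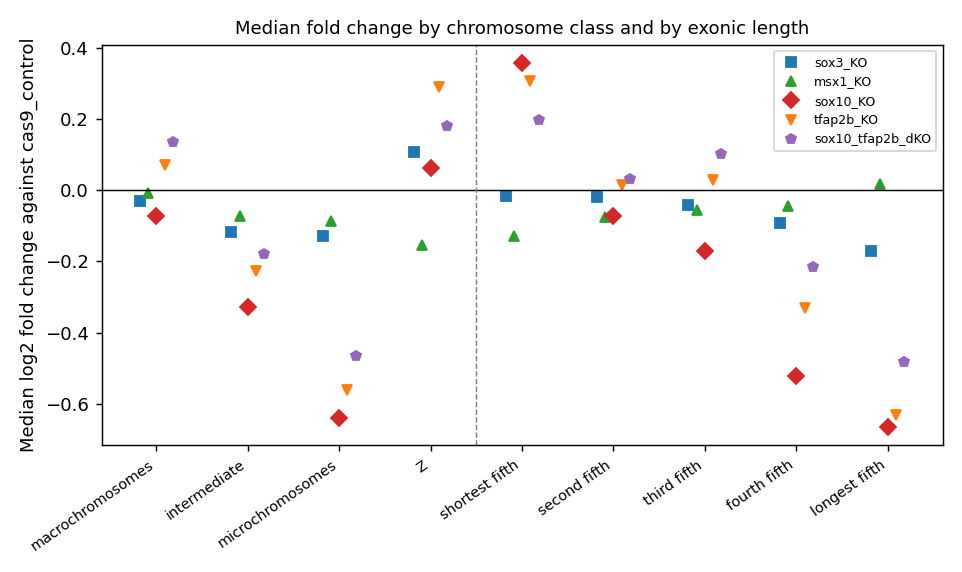
Each symbol is the median log2 fold change (y axis) of the genes of 1 chromosome class or 1 of 5 bins of exonic length (x axis) in 1 targeted group against the control; the dashed line parts the 2 kinds of gene group. Microchromosome medians are -0.64, -0.56 and -0.47 in the sox10, tfap2b and double groups and -0.13 and -0.09 in the sox3 and msx1 groups.

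Genes changed in the sox10 and tfap2b groups overlapped. Both were higher for 2219 genes and both lower for 2455, with 0 in opposite directions, where independent lists would give 494, 782 and 1245. In 30 simulated draws, all libraries including the control were drawn from the control means, and 0 genes were called in common. With no gene changed hardly any gene is called in a group, so this 0 does not gauge the overlap. The covariance of log2 fold changes across genes was 3.73 (simulated 0.522) and their correlation 0.77 (simulated 0.56); genes are not independent replicates. Across the sox10, tfap2b and double groups, 1909 genes were higher in all 3 and 2016 lower in all 3. Over all 5 targeted groups, 22 genes were higher and 6 lower in every one, and 3990 changed in the same direction in at least 3. With the sox10 group set against one control library and the tfap2b group against the other, chosen after seeing the data, 1475 genes were higher in both and 1578 lower (1397 and 1559 with the control libraries exchanged). Independent lists would give 224 and 376 (214 and 377), and the covariance was 3.68 (3.71). For the sox3 and msx1 groups, which shared 31 higher and 7 lower genes, the same split left 0 and 2 genes in common. Few genes were called in the sox3 and msx1 groups against 1 control library, so few could be in common. The covariance of their log2 fold changes was 0.964 with both control libraries and 0.924 and 0.902 after the split. What the 2 control libraries have in common is not removed by this split.

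Between the double and the sox10 group, 866 genes were higher in the double group and 978 lower. ENSGALG00000016833 (chromosome 1, 137595069 to 137603553, 7 exons) had 7.94 ± 1.75 CPM in the double group (SD, n = 3) and 0 counts in the sox10 group, at least 63.2-fold higher. ENSGALG00000031667 (chromosome 3, 309795 to 331507, 4 exons, overlapping another gene and uncertain) had 5.66 ± 0.127 CPM (SD, n = 3) against 0 counts, at least 44.1-fold higher, and 6.97 ± 2.11 CPM in the control (SD, n = 2). Adjusted p was 0.00419 and 0.00373 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and both genes kept their call in 17 of 17 alternatives. ENSGALG00000016662 (chromosome 3, 107785815 to 107811652, 6 exons) was at 0.108 ± 0.188 CPM in the double and 12.8 ± 13.5 CPM in the sox10 group (SD, n = 3 each; log2 fold change -6.79, SE 1.64). ENSGALG00000045740 (chromosome Z, 70663629 to 70668330, 4 exons) had 2 counts in the double group against 7.69 ± 8.02 CPM in the sox10 group (SD, n = 3), a ratio of 141 (95% interval 38.3 to 1170). The adjusted p of the genes that fell was 0.0170 and 0.0277. Both lost their call with the 2 groups fitted alone (0.0617 and 0.0663), with the close pairs summed (0.0604 and 0.0919) and without double replicate 1 or 3 (0.0532 to 0.0787), and the second also without double replicate 2 (0.0941) or sox10 replicate 1 (0.0632; range of the 4 genes over all alternatives 1.19e-06 to 0.0941). Genes with at most 1096 bp of exons had a median log2 fold change of -0.33 and a mean of 0.10, with 117 higher and 313 lower (camera adjusted p = 0.0439, and adjusted p = 0.708 with an estimated correlation). The number of changed genes was 233 with the 2 groups fitted alone and 2833 (584 higher, 2249 lower) with trends of length and chromosome class removed and libraries not recentred. Without double replicate 1, 2 or 3 it was 731, 787 or 1132, and without sox10 replicate 3 it was 1137.

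Between the double and the tfap2b group, 1 gene was higher in the double group and 5 were lower. ENSGALG00000010836 (chromosome 2, 28805158 to 28878615, 13 exons) was at 6.57 ± 2.03 CPM in the double and 46.2 ± 15.6 CPM in the tfap2b group (SD, n = 3 each; log2 fold change -2.81, SE 0.38). ENSGALG00000010722 (chromosome 2, 26674819 to 26685279, 6 exons, overlapping another gene and uncertain) was at 57.0 ± 28.5 and 393 ± 151 CPM (SD, n = 3 each; log2 fold change -2.79, SE 0.44). The other genes that were lower lay on chromosomes 1 (122045082 to 122076797), 8 (4848542 to 4880892) and 19 (5008445 to 5015244), with log2 fold changes of -2.46, -1.91 and -1.70. ENSGALG00000003908 (chromosome 5, 2161580 to 2188356, 19 exons) had 6.42 ± 5.25 CPM in the double group (SD, n = 3) and 0 counts in the tfap2b group, at least 80.2-fold higher. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p of the 3 genes given by ID was 0.0146, 0.0448 and 0.0456. W-linked genes had a median log2 fold change of 1.79 (camera adjusted p = 3.50e-10, and adjusted p = 0.120 with an estimated correlation). Camera called 4 gene groups here, and 0 with an estimated correlation. Among them, genes with at most 1096 bp of exons had a median of -0.21 and those with over 3339 bp 0.10 (camera adjusted p = 0.0296 each). The number of changed genes was 0 with the 2 groups fitted alone (901 genes at an unadjusted p under 0.05 by edgeR, and 197 changed genes by DESeq2 on all libraries). It was also 0 without double replicate 1 (1096 at an unadjusted p under 0.05) or tfap2b replicate 2 (1146), and 2 without double replicate 2 or tfap2b replicate 3. Of the 3 genes, all lost their call without double replicate 1 or 2 or tfap2b replicate 2 (0.0801 to 0.121). ENSGALG00000010722 and ENSGALG00000003908 also lost it without tfap2b replicate 3 (0.102 each), the first also without double replicate 3 (0.0574) and the second without tfap2b replicate 1 (0.101). With the replicate block, these 2 genes lost their call (0.0899 and 0.0776; range of the 3 genes over all alternatives 5.06e-12 to 0.419).

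The double group differed from the sum of the single effects for 5198 genes, 2810 with a positive and 2388 with a negative contrast. ENSGALG00000000371, at 20.4 ± 6.73 CPM in the control (SD, n = 2), had 0 counts in the sox10 and tfap2b groups and 2.36 ± 0.958 CPM in the double group (SD, n = 3). With 0 counts in both single groups, the sum of their effects lies below any count the double group could have. The sign of this contrast was therefore fixed in advance. Neither its call nor its support over the alternatives shows non-additivity of this gene. ENSGALG00000017347 was at 3499 ± 1015 CPM in the sox10, 804 ± 475 CPM in the tfap2b and 229 ± 367 CPM in the double group (SD, n = 3 each). Its double libraries, at 13.7 to 653 CPM with the highest in replicate 1, overlapped the tfap2b libraries (437 to 1341 CPM). In the sox3 group it was at 2026 CPM on average. The adjusted p of the contrast was 2.85e-05 and 0.00806 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The first gene kept its call in 22 of 22 alternatives and the second lost it without control replicate 1 or 2 (0.0676 and 0.0639; range of the 2 genes over all alternatives 7.49e-16 to 0.0849). Against the mean of the single groups, the double group differed for 433 genes (256 higher, 177 lower). With the close pairs summed, 2692 genes were non-additive. With the libraries of these 4 groups alone, 1859 contrasts were positive and 2054 negative, and with trends of length and chromosome class removed and libraries not recentred, 1558 contrasts were positive and 3523 negative.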

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

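None of the tests in this part was chosen after its result was seen. The effect of targeting sox10 differed with and without tfap2b targeting, by the test of the difference itself, for 5198 genes, and this non-additivity is weighed here. If it came from a difference from the control that both single groups share, counted 2 times in the sum of effects, the double group would differ little from the mean of the single groups. That contrast had 433 genes past the threshold, of which 362 were also among the 5198. A shared difference counted 2 times is therefore a candidate explanation for most of the non-additive genes, and what the shared difference is stays open. A biological interaction of SOX10 and TFAP2B, a weaker effect of the single sox10 guide in the double group and a batch were not told apart by these libraries.

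Other divisions of the libraries were also counted. For the double against the sox10 group, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many as 1844 genes, and the highest of the others gave 4. For the double against the tfap2b group, 1 of the 10 splits, the real one, gave as many as 6 genes, and the highest of the others gave 2. With 10 splits no share under 0.05 can be reached. Every other split put libraries of both groups on each side, so any difference between the groups widened the spread and lowered the counts. The distance between the real split and the others is therefore no support.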

How the results depend on the processing

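Both adjustments for length and chromosome class, the runs without Z and W genes, with thinned counts, with close pairs summed, with other references and with separate control libraries, and all alternatives for gene groups by location were chosen after seeing the data. Over the 8 comparisons, 96 of 141 alternative counts of changed genes lay within 1.5 times the reported count. For the genes named by the rule, 544 of 546 alternatives kept the direction and 440 also the call. The 2 that turned were ENSGALG00000043234 and ENSGALG00000017347 in the tfap2b group, with log2 fold changes of -1.22 and -1.33 against the sox3 group, in which both were abundant. Apart from non-additivity, the rule took the largest fold changes among genes without overlap between the libraries compared. Refitting the same groups could hardly turn these directions, so the kept directions were largely fixed by the selection and are no support.

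Fitting only the groups compared gave 4265 genes for sox3, 2267 for msx1, 4175 for sox10, 233 for the double against the sox10 group and 0 (901 at an unadjusted p under 0.05, edgeR) for the double against the tfap2b group. DESeq2 gave 354 for sox3, 1053 for msx1, 3191 for the double against sox10 and 197 for the double against tfap2b. Limma-voom with quality weights gave 4209 for sox3, 5392 for msx1, 8504 for the double group, 657 for double against sox10 and 58 for double against tfap2b. Without a filter, double against tfap2b gave 13. Summing the close pairs, which leaves 1 control sample and thus changes the number of samples along with the spread, gave 1 for sox3, 0 for msx1 (592 at an unadjusted p under 0.05, edgeR), 3608 for sox10, 2506 for tfap2b, 2007 for the double group, 292 for double against sox10, 0 for double against tfap2b (839 at an unadjusted p under 0.05, edgeR) and 2692 for non-additivity. Why the counts moved was not tested for any setting.

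Leaving out 1 library gave 5 to 21 genes for sox3, 42 to 407 for msx1, 4595 to 6734 for sox10, 3420 to 5148 for tfap2b, 3048 to 4804 for the double group, 731 to 2754 for double against sox10, 0 to 8 for double against tfap2b and 3612 to 5731 for non-additivity. The lone library left in a group was assumed to vary like those of the other groups. Genes changed in at least 3 targeted groups numbered 3653 of 3990 at a mean of 5 CPM or more. With each group of a pair against its own control library, genes changed in the same direction numbered 3053 and 2956 for sox10 and tfap2b (4674 with both control libraries), 2705 and 2518 for sox10 and the double group (4300), 2691 and 2528 for tfap2b and the double group (4344), and 0 and 2 for sox3 and msx1 (38). For sox3 and msx1, few genes were called against 1 control library, while the covariance was 0.924 and 0.902 (0.964 with both control libraries). The first adjustment for length and chromosome class shifted whole libraries and gave 2833 genes for double against sox10. It moved the median over all genes for sox10 from -0.31 to 0.41 and the share of changed genes that were higher from 42.8% to 64.9%, for tfap2b from 45.8% to 63.1%, for the double group from 45.8% to 61.5%, for double against sox10 from 47.0% to 20.6% and for positive non-additivity from 54.1% to 30.7%. After this was seen, libraries were recentred in the second adjustment, which left the share for sox10 at 42.5%. RLE scaling moved the median log2 value of the non-additivity contrast from 0.32 to 0.20.

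Replicate numbers were checked as a possible pairing. Same-numbered libraries deviated together little (36 correlations of -0.086 to 0.148, 2 of them over 0.1). In groups of 2 libraries the deviations mirror each other, so these correlations are not independent. They gave no sign of a strong pairing, but a weak effect of a shared day or batch could not be seen this way. With the number as a block, double against tfap2b gave 3 genes, 2 of them among the 6 reported, and the other counts stayed within 1.5 times (79 for sox3, 362 for msx1, 6215 for sox10, 5095 for tfap2b, 4879 for the double group). The alternatives set for the targeted genes and the gene lists were not run, since IDs were not paired with names. The simulation, run at 1 depth and 1 number of replicates, recovered 6% of 2-fold changes for sox10.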

Other observations

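The tests of the female share of embryos, of single W genes, of the shared spread and of low-abundance transcripts, the recentred form of the length adjustment and the reading of the batch test were chosen only after the results were seen. The 3 genes of the chromosome 14 region (12156905 to 12164434) and the chromosome 1 gene ENSGALG00000017347 together took 1.01% to 1.77% of counts in the sox10 libraries and 1.03% and 1.62% in the sox3 libraries. In the tfap2b group they took 0.251% to 0.567%. In the double group, replicate 1 held 0.356%, against 0.00668% and 0.0109% in replicates 2 and 3. In the msx1 group, replicate 3 held 0.0872%, against 0.000804% and 0.000942% in replicates 1 and 2. The control libraries held 0.000196% and 0.000280%. Which cells these transcripts mark was not analysed here. The region was singled out after its values were seen.

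Counts on W genes, which only female birds carry, ranged from 74.1 CPM in tfap2b replicate 3 to 843 CPM in msx1 replicate 2, and counts on Z genes from 3.48% in msx1 replicate 1 to 5.63% in tfap2b replicate 2. In msx1 replicates 1 and 2, all 16 W genes with at least 200 counts were higher than in replicate 3 (median fold 3.70, range 2.87 to 5.36), which argues against a change of 1 or 2 W-linked genes. Over 486 Z genes, the median log2 ratio to replicate 3 lay below that of genes on chromosomes 1 to 5 by a difference of -0.36 in replicate 1 and -0.30 in replicate 2. A higher share of female embryos in these libraries is a candidate explanation. Of the genes changed in the msx1 group, 6 higher and 7 lower lay on Z and 0 on W.

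Changed genes numbered 6538, 5430 and 5243 in the sox10, tfap2b and double groups but 91 and 399 in the sox3 and msx1 groups. Against a trend with length and chromosome class as the whole cause, 6415 genes were changed in the sox10 group after its removal, 5791 of them in the same direction as before (6399 and 5015 in the first form, without recentring), and against a loss of low-abundance transcripts, 68.2% of genes with at least 50 CPM in the control changed. With only the compared groups in the fit, 4265 genes changed for sox3, 2267 for msx1 and 4175 for sox10. In that setting no gap in counts was left between sox3 and sox10. The estimate of spread shared by all groups may thus account for at least part of the gap. These fits also changed the filter and the number of libraries. The sox3 and control replicates were among the closest pairs. If they were repeat libraries, the 4265 genes for sox3 rest on technical spread only and do not bear on the gap. The interquartile range of log2 fold changes does not rest on the estimate of spread shared by all groups. It was still 0.83 wide in sox3 and 0.88 in msx1, against 2.86, 2.36 and 2.30 in the sox10, tfap2b and double groups. Of the sox10 calls 68.2% also held against the sox3 and msx1 groups, above the bound set beforehand for an unrecorded batch. An effect of targeting sox10 would give the same result, so this test could not tell a batch from the targeting. A batch along the first principal component would coincide with the groups, since no group lay on both sides of it.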
